A study of Drosophila melanogaster with 2 samples.

How the data were processed

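Chromatin immunoprecipitation with sequencing was carried out on whole larvae in 2 biological replicates of 1 group, per the labels, with chromatin sheared by sonication to fragments of 200 to 800 bp. The sex of the larvae was not recorded in the labels. The deposited files are peak lists in narrowPeak layout. Per the labels and file listings, a list was called for each replicate against a control library, and another on both replicates pooled, and a further list was thresholded on the irreproducible discovery rate from these. Each exists for the dm6 and the dm3 genome builds, from separate alignments. The aligner and the peak caller are not given in the sources used here. The control library was not analysed here.

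Each peak carries a signal value, which is the value of the authors' caller for that peak on a scale that is not stated, and it was used only to rank and describe peaks. Each peak also carries a -log10 q-value from the deposited lists, which reaches a ceiling of 4.12 that 90.5% of the dm6 thresholded peaks share, so it was not used for ranking. The replicate and pooled lists end at 30000 peaks and include background, so their last peaks depend on that limit rather than on a test. The 7223 thresholded peaks were the 7223 highest-signal peaks of the pooled list, with a lowest signal of 109, so the thresholded list is a list of the pooled data, and replicate differences are seen only in the replicate lists. In 27 cases a peak repeats the interval of another with a different summit. The dm3 thresholded list held 7030 peaks. No peak of the dm6 lists lay outside X, 2L, 2R, 3L, 3R and 4.

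Peaks were read in dm6 coordinates and set against the Release 6 reference sequence, which is the dm6 build, and the Ensembl BDGP6 annotation, release 115; every peak lay within the length of its arm. Positions are given counting from 1. The main tests, the fixed lists and motifs and the rule for named genes were set before the data were examined. Replicate overlap took the 7223 highest-signal peaks of each replicate and counted summits within 200 bp, against 1000 circular shifts. Signal at a thresholded peak in a replicate was that of its strongest relaxed peak with a summit within 200 bp. A summit was placed in the first that applied of promoter (within 500 bp of any start site), coding exon, untranslated region, other exon, intron and intergenic, and was compared with 1000 random placements on the same arm outside unknown bases. Coding exons with promoters included were compared with 100 such placements. Peaks per arm were compared with sequence length by an exact binomial test.

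Motifs and 6-mers were scanned on both strands in 101 bp around each summit and in an equal window centred 400 bp away at lower coordinates, and tested by exact McNemar tests. Gene lists were tested by Fisher's exact test among the 13968 protein-coding genes of the 6 arms and Y. As an alternative, the number of genes with a summit within the gene or 5 kb of it was ranked among 10000 random lists matched on gene length, a two-sided permutation test. Of 569 list entries, 19 were matched through an older symbol, a step added after the data were examined, and 3 had no protein-coding match. The OdsH region was the gene with 10 kb on either side, ranked among 10000 random windows on X. Adjusted p-values are Benjamini-Hochberg values within each family, and the threshold was 0.05, two-sided. The interval of the correlation is a Fisher z interval across peaks.

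Named genes were the coding genes nearest to the 20 strongest thresholded peaks, OdsH and unc-4, and the 4 bound members with the strongest summit of each list past the threshold, along with all motifs past it and the 10 6-mers with the smallest p. Alternatives were other distances, overlap rules, windows, flanks and backgrounds, the strongest peaks alone, peak lists of each replicate alone, and the dm3 lists. Replicate 1 or 2 was left out by taking the 7223 strongest relaxed peaks of the other. The overlap and the correlation need both replicates, so neither could be left out there. With 1 group there was no comparison between groups, no control sample among those used, and no test across samples; each p-value is over peaks or genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The test functions were tested on simulated data, where all 40 of 40 planted gene lists and 0 of 160 unrelated lists were called.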

Results

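Binding of a GFP-tagged form of the homeodomain protein OdsH was measured by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster larvae in the wandering stage of the third instar. OdsH (FBgn0026058) lies on X beside its paralog unc-4 (FBgn0024184), which encodes a homeodomain protein of motor neurons, and is known as a gene of hybrid male sterility. The larvae came from a transgenic line carrying OdsH fused at its C terminus to GFP, and the precipitation used an antibody against GFP. There was 1 group with 2 biological replicates, so no condition was compared with another. The questions addressed were where in the genome the tagged protein was bound, how well the replicates matched, and which sequences and genes lay at the bound sites. Each replicate list, and a list called on both replicates pooled, held 30000 relaxed peaks, and the list thresholded on the irreproducible discovery rate held 7223 peaks (dm6). The median width of the thresholded peaks was 444 bp, and together they covered 2.06% of the 6 chromosome arms. The numbers of reads behind the peaks were not given in the sources used here, so the depth is unknown. All intervals on shares cover counting error over peaks or genes only.

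The replicates placed their strongest peaks at the same sites. Of the 7223 highest-signal peaks of replicate 1, 6015 (83.3%, 95% Wilson interval 82.4 to 84.1) had a summit within 200 bp of one of the 7223 highest-signal peaks of replicate 2. Circular shifts of replicate 2 along each arm gave a mean of 2.07% and at most 2.63% (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Signal at the thresholded peaks was correlated between the replicates, with Spearman's rho of 0.822 over the 7173 peaks that had a partner in both (interval 0.815 to 0.830). That correlation is across peaks, which are not independent replicates. Replicate 2 had the higher signal, with a median log2 ratio to replicate 1 of 0.26 and an SD over peaks of 0.45. A partner was missing for 29 thresholded peaks in replicate 1 and for 21 in replicate 2, and 5939 (82.2%) ranked among the 7223 highest in both replicates. The thresholded peaks were themselves selected from these replicates, on the irreproducible discovery rate, and are the strongest pooled peaks. The correlation and this share are therefore not independent evidence of agreement. Neighbouring thresholded peaks could also share a partner.

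**Figure D1:**
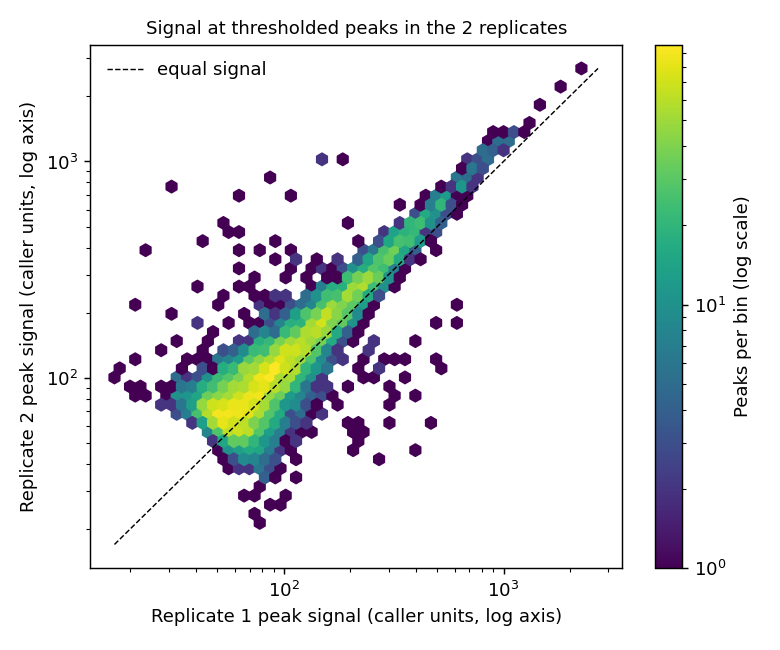
Signal of each thresholded peak in replicate 1 (horizontal) and replicate 2 (vertical), in the caller's units on log axes, with colour giving the number of peaks per bin and the dashed line equal signal. The 7173 peaks with a partner in both replicates lie along the diagonal (Spearman's rho 0.822), with a median shift of 0.26 on the log2 scale towards replicate 2.

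The strongest peaks lay mostly at promoters, but the 2 strongest were in introns, of ush and of CG11050. The first spanned 2L 480566 to 481381, with its summit at 481061 in an intron of ush, which encodes a cofactor of GATA factors, and 1373 bp upstream of the start site of cbt (FBgn0043364), which encodes a zinc finger transcription factor. Its signal was 4906 in the pooled list, 2260.3 in replicate 1 and 2691 in replicate 2, and it ranked 1 in all 3 lists. The reference sequence around its summit, from 481041 to 481081, was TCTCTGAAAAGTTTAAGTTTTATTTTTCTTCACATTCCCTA. The next was at 2L 6612403 to 6612952, in an intron of CG11050 (FBgn0031836), with a pooled signal of 4058. The peak ranked 3 was at the promoter of CG14100 (FBgn0036889, 3L 19590411 to 19590853), 87 bp from the start site, with a pooled signal of 3180.0. Its summit sequence, from 19590591 to 19590631, was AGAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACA.

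Of the 20 strongest peaks, 13 had their summit at a promoter and 5 in an intron. The promoter peaks included those of Ugalt, a UDP-galactose transporter gene (FBgn0024994, X 2703673 to 2704103, pooled signal 2634), gish, a casein kinase gene (FBgn0250823, 3R 16280486 to 16280976, 2571), and PNPase, which encodes a mitochondrial RNA-processing enzyme (FBgn0039846, 3R 31404475 to 31404865, 2347). Others were those of the small heat shock protein gene Hsp27 (FBgn0001226, 3L 9383678 to 9384119, 2233), larp, which encodes an RNA-binding protein (FBgn0261618, 3R 28326359 to 28326818, 2237), and Chro, which encodes a chromodomain protein (FBgn0044324, 3L 22878694 to 22879105, 2129.5). CG1888, Fkbp14, CenG1A, Tcs5 and CG18549 were the coding genes nearest to the other promoter peaks, along with eEF1gamma, whose peak lay 153 bp from the start site of a non-coding RNA gene, lncRNA:CR31044. Intron peaks lay in Lk6, a kinase gene (FBgn0017581, 3R 11760835 to 11761268, 2529.9), and in CG32772 (FBgn0052772, X 4910095 to 4910665, 2356). The intron peak nearest to CG16753 lay in CG32486, 5718 bp from the CG16753 start site. The peak inside osa, which encodes a subunit of the Brahma chromatin remodelling complex, was in a non-coding exon where osa overlaps the RNA gene lncRNA:CR46035, and the peak nearest to CG13323 was intergenic. All 20 ranked 23 or better in replicate 1 and 20 or better in replicate 2.

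Summits were concentrated at promoters and nearly absent from coding exons. A promoter, within 500 bp of any annotated start site, held 3135 of the 7223 summits (43.4%, 95% Wilson interval 42.3 to 44.5), against 13.6% ± 0.407 (SD over 1000 placements) for random positions on the same arms, 3.19 times as many (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Coding exons outside promoters held 14 summits (0.194%, interval 0.115 to 0.325) against 13.9% of random positions. With promoters included, 47 summits (0.651%) lay in coding sequence, against 17.0% of random positions. Untranslated regions held 1.51% against 4.99%, and intergenic sequence 15.6% against 27.3%, each with permutation p = 0.002. Introns held 38.3% against 39.4% (permutation p = 0.0819) and other exons 0.955% against 0.816% (permutation p = 0.222), neither past the threshold. These class p-values were not adjusted over the 6 classes.

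The promoter share also rose with peak rank. It was 54.6% among the 500 strongest peaks. Among the 7223 lowest-ranked relaxed peaks that overlapped no thresholded peak it was 21.4% (interval 20.5 to 22.4), and 5.48% of those summits lay in coding exons. Summits near coding genes lay mostly upstream of the start site. Of 3604 summits within 1 kb of the start site of a coding gene, 2544 (70.6%, interval 69.1 to 72.1) were upstream (exact two-sided binomial p = 9.53e-139), with a median position of -93.5 bp and quartiles of -227 and 37 bp. That test takes both sides as equally likely and summits as independent, and no random placement was made for it. The coding exons of a gene, nearly free of summits, lie downstream of its start site, so the excess may partly restate their avoidance.

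**Figure D2:**
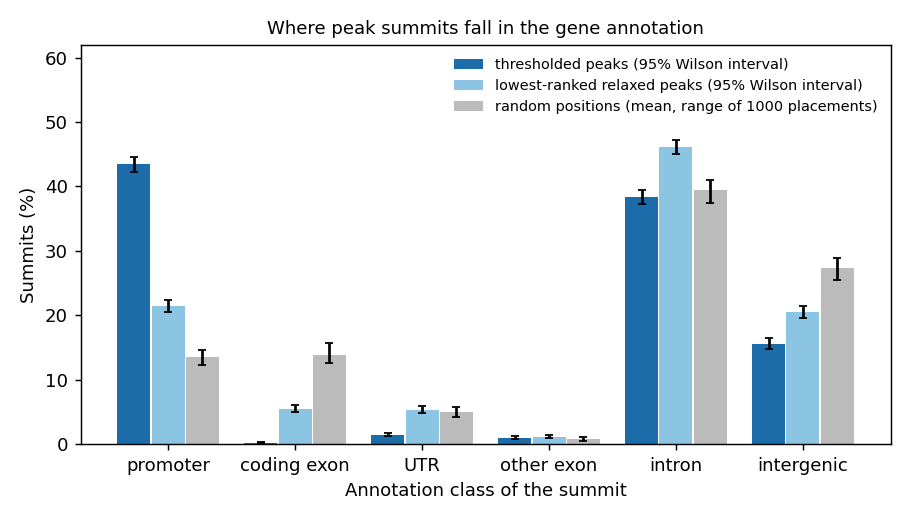
Percentage of summits in each annotation class for the thresholded peaks, for the lowest-ranked relaxed peaks (bars with 95% Wilson intervals) and for random positions (mean, with the range of 1000 placements). Promoters held 43.4%, 21.4% and 13.6% of them, and coding exons outside promoters 0.194%, 5.48% and 13.9%.

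Chromosome 4 was poor in peaks, and the other arms differed little from their share of sequence. Chromosome 4, a small and largely heterochromatic chromosome, held 15 thresholded peaks, 0.208% (95% Wilson interval 0.126 to 0.342) against 0.996% of the sequence (exact binomial adjusted p = 4.49e-15 over the 6 arms). X held 1193 peaks, 16.5% (interval 15.7 to 17.4) against 17.6% of the sequence (exact two-sided binomial p = 0.0188). Arm 2L held 18.9% against 17.6% (exact binomial adjusted p = 0.00851) and 3L 22.4% against 20.9% (adjusted p = 0.00685), while 2R and 3R did not pass the threshold. The binomial test treats peaks as independent, which neighbouring peaks are not. Other backgrounds, not tested for these arms, changed the reading. 2L held 19.1% of coding genes, above its share of peaks, and 17.8% of the lowest-ranked relaxed peaks. 3L held 19.6% of coding genes, and 23.2% of the lowest-ranked relaxed peaks, above its share of thresholded peaks. Chromosome 4 held 0.574% and 0.623%, so its deficit was smaller against them but remained. The deficit on X depended on the comparison: X holds 15.7% of coding genes, fewer than its share of peaks (p = 0.0730), and the difference from the lowest-ranked relaxed peaks (17.7% on X) did not pass the threshold (Fisher exact p = 0.0604), nor did that of the 3611 strongest peaks from sequence length (exact binomial p = 0.162).

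Sequence at the summits was rich in A and T, and homeodomain sites were more frequent there than in the flanks, but not more frequent than at random positions of equal A and T content. The homeodomain core TAAT occurred within 50 bp of 75.0% of summits and in 53.6% of windows of equal size 400 bp away at lower coordinates (exact McNemar adjusted p = 8.94e-152). TAATTA, the palindromic site of many homeodomain proteins, occurred at 9.72% (95% Wilson interval 9.06 to 10.4) against 5.79% (exact McNemar adjusted p = 8.33e-18), and TAATTG at 9.93% against 8.31% (adjusted p = 0.0017). Pairs of TAAT sites facing each other with a spacing of 2 or of 3 bases, as bound by dimers of paired-class homeodomain proteins, each occurred at 1.25% of summits, against 0.512% (exact McNemar adjusted p = 1.01e-05) and 0.526% (adjusted p = 1.53e-05). The composite site of Exd and Hox proteins occurred at 8.20% against 5.41% (exact McNemar adjusted p = 1.38e-10). The windows held 65.6% A and T at summits, 55.6% in the flanks and 57.8% over the arms.

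In all, 11 of the 28 fixed motifs were more frequent at summits and 9 less frequent (exact McNemar tests, two-sided, Benjamini-Hochberg adjusted over the motifs). The TATA box sequence TATAAA, on either strand and anywhere in the window, was found at 1558 summits (21.6%) and in 724 flanks (exact McNemar adjusted p = 9.99e-80). It was not tied here to a position from a start site. Sites of the housekeeping promoter factors DREF (1.11% against 0.318%, exact McNemar adjusted p = 4.72e-08), M1BP (0.498% against 0.235%, adjusted p = 0.0162) and BEAF-32 (4.93% against 3.28%, adjusted p = 2.89e-06) were more frequent, as was the GATA factor site (3.71% against 2.91%, adjusted p = 0.0115). The CA repeat was less frequent, at 1.69% against 3.85% (exact McNemar adjusted p = 7.27e-15). The other less frequent motifs were those of Zelda (0.388% against 0.803%), GAGA factor (2.05% against 2.84%), Pho (2.89% against 3.81%), Grainyhead (0.125% against 0.305%), the nuclear receptor site AGGTCA (1.84% against 2.51%) and the E-boxes CAGCTG (3.90% against 5.14%), CACCTG (2.73% against 3.65%) and CACGTG (0.665% against 1.26%), with exact McNemar adjusted p from 0.000755 to 0.0412. The call for GATA was lost without replicate 1 (exact McNemar adjusted p = 0.148) and without replicate 2 (adjusted p = 0.0615), as were those for CAGCTG without replicate 1 (adjusted p = 0.0675) and for AGGTCA without replicate 2 (adjusted p = 0.0920). With the 3611 strongest peaks the calls for M1BP (exact McNemar adjusted p = 0.213), GATA (adjusted p = 0.487) and AGGTCA (adjusted p = 0.154) were lost, and that for TAATTG was lost with flanks at 1 kb (adjusted p = 0.107) and against the lowest-ranked relaxed peaks (Fisher exact adjusted p = 0.147). GAGA factor sites were not less frequent against flanks at 1 kb or against the lowest-ranked relaxed peaks, where the difference was 0.0554 percentage points. The calls for Zelda, Grainyhead, CACCTG and CACGTG were each lost with another flank, comparison or peak set.

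Of all distinct 6-mers, counted with their reverse complements, 530 were more frequent at summits and 1084 less frequent. All 36 made of A and T alone were more frequent, while of the 720 with at least 4 G or C, 2 were more and 682 less frequent. The 10 with the smallest p were AAATAT (32.7% against 14.5%, exact McNemar adjusted p = 2.13e-142), TTAAAA (30.5% against 13.4%), ATTTAA (27.0% against 11.2%), ATTTTA, AAAATA, TAAATA, ATATTA (20.2% against 6.96%), AATATA, TTTAAA (19.9% against 6.95%) and AAATAA. Against random positions of equal A and T content, a comparison chosen after the data were examined, TAATTA was less frequent at summits (9.72% against 11.3%, Fisher exact adjusted p = 0.0110), as was TAATTG (9.93% against 12.4%). The random set held as many positions as there were summits, and variation between draws of this set is not shown. DREF, M1BP and GATA sites were more frequent in this comparison too, and Pho sites less frequent. The calls for BEAF-32 (4.93% against 4.17%, Fisher exact adjusted p = 0.0868) and the TATA box (adjusted p = 0.377) were lost. The calls for TAAT (75.0% against 75.9%, Fisher exact adjusted p = 0.377), the Exd and Hox composite (8.20% against 8.92%, adjusted p = 0.258) and the TAAT pairs spaced by 2 and 3 (adjusted p = 0.800 and 0.258) were lost and their direction turned. The calls for Zelda, Grainyhead, CACCTG, CACGTG, AGGTCA and the CA repeat were lost as well. GAGA factor sites (2.05% against 1.07%) and CAGCTG (3.90% against 1.97%) turned to an excess. The excess of DREF sites was not seen at the 4088 peaks over 500 bp from any start site, where summits and flanks differed by -0.0245 percentage points (exact McNemar adjusted p = 1).

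**Figure D3:**
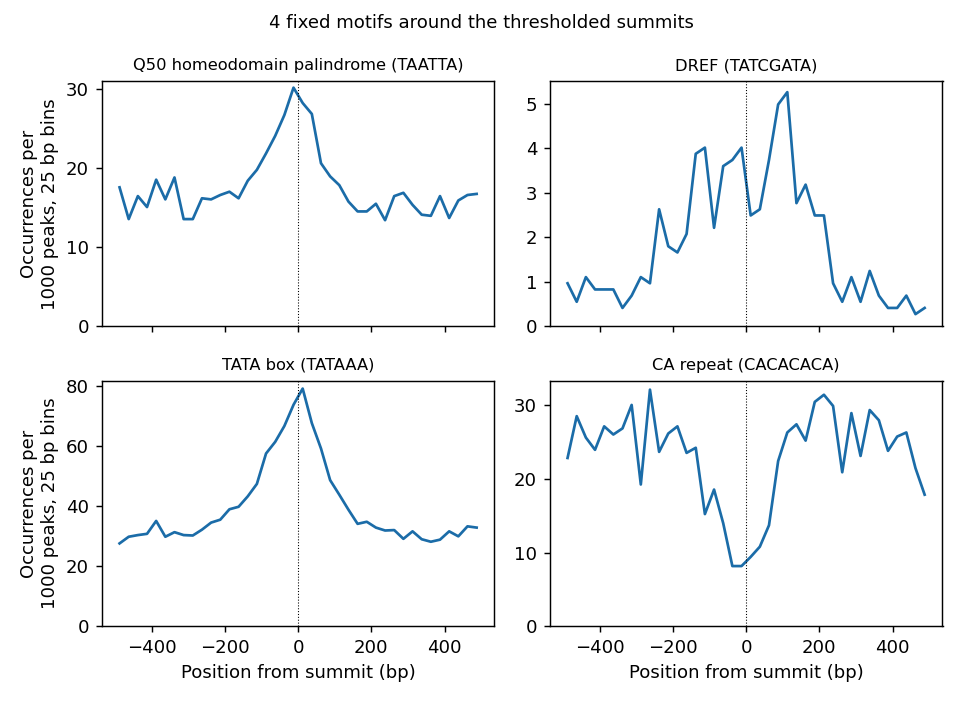
Occurrences of 4 fixed motifs per 1000 thresholded peaks in bins of 25 bp, by position from the summit at lower (negative) and higher coordinates. TAATTA and the TATA box sequence TATAAA peaked at the summit, DREF sites were spread over the central region, and CA repeats were depleted at the summit.

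Ribosomal protein genes and a list of housekeeping genes were bound more often than other genes. A gene was taken as bound when a thresholded summit lay within 1 kb of one of its start sites, which held for 3910 of 13968 protein-coding genes (28.0%). Bound in this sense means a called peak. Whether open chromatin at promoters raised the shares of any list was not tested, since the control library was not analysed here. Of 64 ribosomal protein genes, 52 were bound (81.3%, exact 95% interval 69.5 to 89.9) against 27.7% of other genes (Fisher exact adjusted p = 2.41e-17), and the strongest summit of each of the 52 was at a promoter. The strongest were RpL7 (FBgn0005593, 2L 10200889 to 10201172, pooled signal 769.9, replicates 374 and 403), RpS27 (FBgn0039300, 3R 25247371 to 25247655, 725), RpL32 (FBgn0002626, 3R 30046098 to 30046434, 545) and RpL14 (FBgn0017579, 3L 8600797 to 8601051, 486). Of 21 housekeeping genes, 16 were bound (76.2%, interval 52.8 to 91.8, Fisher exact adjusted p = 7.43e-05). The strongest were at the glycolytic genes Gapdh2 (FBgn0001092, X 15867756 to 15868221, pooled signal 2129, replicates 1034 and 1103) and Pgk (FBgn0250906, 2L 2751815 to 2752343, 721), the actin gene Act5C (FBgn0000042, X 5900007 to 5900331, 716) and Polr2B, which encodes an RNA polymerase II subunit (FBgn0262955, 3R 14125505 to 14125839, 605).

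Larval cuticle genes were not bound, and genes of other homeodomain proteins were bound rarely. None of 23 larval cuticle genes had a summit within 1 kb of a start site (0 of 23, exact interval up to 14.8%, Fisher exact adjusted p = 0.00591). The call was lost with the 3611 strongest peaks alone (Fisher exact adjusted p = 0.195), where fewer genes were bound. Of 61 other homeobox genes 7 were bound (11.5%, interval 4.74 to 22.2, Fisher exact adjusted p = 0.0153). The strongest were at tin, which specifies heart mesoderm (FBgn0004110, 3R 21378586 to 21378940, pooled signal 834), E5 (FBgn0008646, 3R 13875500 to 13875943, 179), ro, a gene of eye development (FBgn0003267, 3R 26881533 to 26881976, 145), and bcd, the anterior determinant of the embryo (FBgn0000166, 3R 6759457 to 6759900, 143). This call was lost without replicate 1 (Fisher exact adjusted p = 0.165).

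Ecdysone response genes and heat shock genes were bound more often than other genes, but the calls depended on the replicate and on the setting. The ecdysone response list is named for the steroid hormone that drives metamorphosis. It also holds genes of the hormone's synthesis (dib, nvd, phtm, sad, spok and sro), of which only sro was bound. Of the 30 genes of the list, 16 were bound (53.3%, exact interval 34.3 to 71.7, Fisher exact adjusted p = 0.0174). Among them were Eip75B (FBgn0000568, 3L 17999560 to 17999978, pooled signal 975, replicates 432 and 561), Ldh (FBgn0001258, 3L 6262684 to 6263096, 901), Eip74EF (FBgn0000567, 3L 17619345 to 17619788, 250.1) and usp, which encodes a subunit of the ecdysone receptor (FBgn0003964, X 2041228 to 2041671, 248). The Fisher exact adjusted p was 0.0603 without replicate 1 and 0.103 without replicate 2, 0.264 with summits within 500 bp and 0.586 with the 3611 strongest peaks. Against random lists matched on gene length, with bound taken as a summit within the gene or 5 kb of it, the permutation adjusted p was 0.122. Of 17 heat shock and stress genes 10 were bound (58.8%, interval 32.9 to 81.6, Fisher exact adjusted p = 0.0449), with 9 distinct strongest summits between them. Besides Hsp27 they were led by Hsp26 (FBgn0001225, 3L 9377386 to 9377717, 759), Hsp83 (FBgn0001233, 3L 3192967 to 3193251, 675) and CG4456 (FBgn0001228, 3L 9373507 to 9373650, 280.3), whose summit is also the one nearest to Hsp22. The Fisher exact adjusted p of this list was 0.00247 without replicate 1, 0.0532 without replicate 2, 0.0856 when only current gene symbols were matched, and 0.0599 to 0.187 under the other settings of that test that ended the call. Against the lists matched on gene length the permutation adjusted p was 0.0948. The Hsp70 genes that were not bound are near-identical copies, at which reads may not be placed uniquely, so their state is uncertain.

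The other 18 of the 24 lists did not pass the threshold for summits within 1 kb of a start site, with bound shares from 0% to 43.5%. Among them, Polycomb and heterochromatin protein genes were bound in 10 of 23 cases (Fisher exact adjusted p = 0.232), genes of neuronal function in 3 of 26 (adjusted p = 0.209) and motor neuron transcription factor genes in 0 of 10 (adjusted p = 0.209). Against the lists matched on gene length, Notch pathway genes were bound more often (23 of 27, against a mean of 14.6 in the matched lists, permutation adjusted p = 0.0048). In the same comparison motor neuron transcription factor genes (2 of 10, against 6.77, permutation adjusted p = 0.0151) and gut genes (2 of 17, against 9.13, adjusted p = 0.0036) were bound less often. That test also treats genes as independent, although 11 of the 27 Notch pathway genes lie in the E(spl) cluster (3R 25997621 to 26041008) and can share summits within 5 kb. Fisher exact tests were two-sided and adjusted by Benjamini-Hochberg over the 24 lists, and they treat genes as independent, although neighbours can share a peak.

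**Figure D4:**
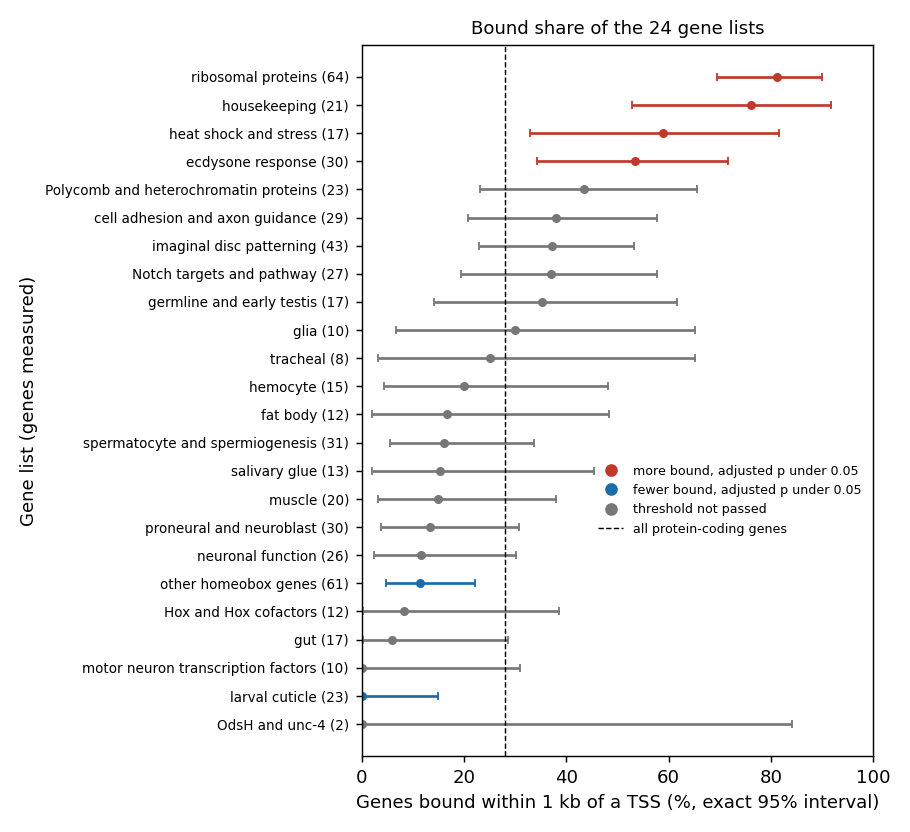
Percentage of genes in each of 24 lists with a thresholded summit within 1 kb of a start site, with exact 95% intervals, the number of genes measured in parentheses and the dashed line at the 28.0% of all coding genes. Lists more often bound (red) ranged from 53.3% to 81.3%, and the lists less often bound (blue) were at 11.5% and 0%.

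The OdsH gene itself held thresholded summits, but not at its start site. The tagged transgene carries extra copies of this region, so copy number could add to the signal there. Whether it did was not tested, since the control library was not analysed here. OdsH, on the forward strand at X 17791010 to 17814011, had 2 thresholded summits inside, both in introns. The stronger spanned X 17802714 to 17803091, with a pooled signal of 711, replicate signals of 289 and 430.3, and the sequence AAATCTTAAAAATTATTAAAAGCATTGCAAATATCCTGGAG from 17802888 to 17802928. The other spanned X 17807130 to 17807332 (pooled signal 454). A further 5 lay downstream of the gene, with summits from 17814298 to 17820409 and pooled signals from 118 to 431. The paralog unc-4, at X 17768569 to 17778708, had none inside. The nearest summit was 11898 bp from a start site of OdsH and 7844 bp from one of unc-4. Within 10 kb of OdsH there were 7 thresholded summits, against a mean of 2.21 ± 2.66 (SD) in 10000 random windows of equal length on X, a difference that did not pass the threshold (two-sided permutation p = 0.158). Relaxed peaks within 10 kb did not pass it either. The pooled list held 22 against a mean of 9.55 (two-sided permutation p = 0.165). Replicate 1 held 21 against 9.75 (permutation p = 0.231) and replicate 2 held 23 against 9.06 (permutation p = 0.113). With a margin of 20 kb there were 13 thresholded summits against a mean of 3.25, past the threshold (permutation p = 0.0408).

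**Figure D5:**
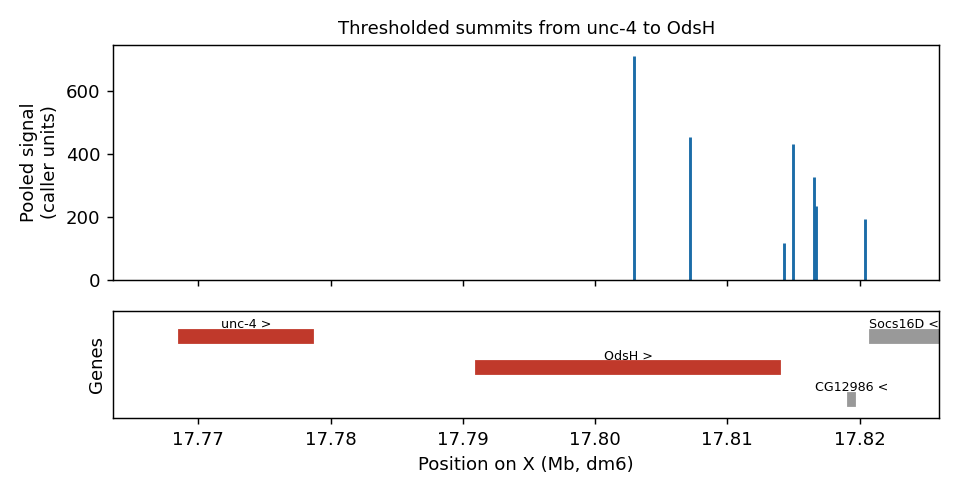
Thresholded summits (bars, pooled signal in the caller's units) and protein-coding genes along X from upstream of unc-4 to downstream of OdsH (dm6), with > and < marking the strand. The 2 summits inside OdsH had signals of 711 and 454, and none lay inside unc-4.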

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

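The dm3 lists, which served only as alternatives for the replicate overlap, the correlation and the X share, held peaks on sequence outside X, 2L, 2R, 3L, 3R and 4. The pooled dm3 list had 22 such peaks, above the limit of 3 that a count of 0 allows, and 2 of them were in the thresholded dm3 list. They lay on unplaced sequence (4 on U and 7 on Uextra) and on heterochromatic scaffolds, 6 of them on that of X. The strongest had a pooled signal of 158 and ranked 4516. The replicate lists held 26 and 16 such peaks, and none lay on the heterochromatin of Y. The corresponding dm6 lists held none outside the 6 arms. The 2 builds can name and place the same sequence differently. Whether the sequence of these scaffolds lies within the arms of dm6 was not examined, and whether it was searched there is not given in the sources used here. No explanation was tested.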

How the results depend on the processing

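The comparison with equal A and T content, the removal of ribosomal protein and housekeeping genes and the match by current symbols only were chosen after the data were examined. The replicate overlap (69.3% to 86.2%) and the promoter share (33.4% to 54.2%) kept their direction and passed the threshold under every alternative tried. The N highest pooled peaks are the thresholded peaks themselves, so that alternative could change nothing. The correlation of 0.822 became 0.831 with partners within 100 bp, 0.863 over the 3611 strongest peaks, 0.877 as Pearson's r on log2 signal and 0.833 with dm3. The X share fell short of the threshold for the 3611 strongest peaks (16.7% on X) and against the lowest-ranked peaks (16.5% against 17.7%), and against the share of coding genes the same 16.5% was higher than the comparison, 15.7%. Without one replicate it was 16.3% to 16.7%. The number of 6-mers more frequent at summits ran from 424 to 582 around 530. The number of motifs more frequent at summits was 8 to 12 except against equal A and T content, where it was 5. The OdsH region held 13 summits with a margin of 20 kb, past the threshold there, and 6 to 8 without one replicate.

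The number of lists more often bound, 4, was 2 with the strongest 3611 peaks, 2 with summits within 500 bp, 2 to 3 without one replicate, 3 by current symbols only, 5 with summits within the gene or 5 kb (where 3 lists were less often bound, against 2), 3 against lists matched on gene length (4 less often bound), and 1 without ribosomal protein and housekeeping genes, where 2 of the 4 lists were taken out and heat shock genes missed the threshold. Of the single lists, 14 comparisons lost and 6 gained a call, and of the single motifs 33 lost a call in the same direction, 14 turned direction and 10 gained a call. Against equal A and T content, the difference in percentage points (summit minus comparison) changed sign to -1.56 for TAATTA, -2.52 for TAATTG, -0.886 for TAAT, -0.0831 and -0.318 for its pairs spaced by 2 and 3, -0.720 for the Exd and Hox composite, 0.983 for GAGA factor, 1.94 for CAGCTG, 0.277 for CACCTG, 0.0692 for Grainyhead and 0.0277 for the CA repeat. GAGA factor also changed sign, to 0.0554, against flanks at 1 kb and against the lowest-ranked peaks, and DREF to -0.0245 at peaks over 500 bp from a start site. The matched comparison equalises the A and T content of the windows by construction, but not their location. The cause of these changes of sign was not tested. Depth limits could not be examined, since read numbers were not used here.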

Other observations

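The rank of TAATTA among A and T 6-mers was tested after its result had been seen, and the comparison of strong and weak peaks at equal A and T content was added after the unadjusted difference and the A and T content of those peaks had been seen. Some genes held many bound sites. The most thresholded summits within a coding gene were 25, in sbb, which encodes a zinc finger protein (2R 18278198 to 18357296), and in the much longer kirre, a gene of myoblast fusion (X 2740384 to 3134532). At the mean density of summits 4.27 and 21.3 would be found, so sbb, not kirre, stood out. Tet held 21 where 5.02 would be found, shn, a gene of Dpp signalling, 20 against 3.15, the ecdysone response gene Eip75B 19 against 6.15, ush 18 against 3.48, and Mnt, which encodes a partner of Max, 16 against 1.61. In all 2209 coding genes held a summit and 41 held 10 or more. These genes were chosen after their values were seen.

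In 4 of 7 classes, genes were near bound sites more often than any random placement gave. These were protein-coding genes (28.0%, placements at most 12.6%), genes annotated as ncRNA (15.7%, at most 12.3%), and snoRNA and tRNA genes, both with lower shares than coding genes. Of 269 snoRNA genes, 59 (21.9%, 95% Wilson interval 17.4 to 27.3) had a summit within 1 kb of a start site, against a mean of 10.2% in 100 random placements of the peaks, the highest of which gave 19.0%. Of 290 tRNA genes 50 did (17.2%, interval 13.3 to 22.0), against 10.6% and at most 16.2%. Of 32 snRNA genes 8 did (25%, interval 13.3 to 42.1), which did not exceed the highest placement, also 25%. Pseudogenes were at 4.48% (12 of 268), below the lowest of the placements, 5.60%. None of 99 annotated rRNA genes had a summit, but placements ranged from 0% to 27.3%. The placements did not keep peaks near coding promoters. Peaks of neighbouring coding genes may therefore contribute to the shares of the non-coding classes, which was not tested.

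Whether bound promoters carry the elements of housekeeping promoters was examined at the most upstream start site of each gene. The same peaks had already shown DREF, M1BP and BEAF-32 sites to be more frequent at summits. The shares for these sites are therefore another view of that result and not independent support. Promoters with a DREF, M1BP or BEAF-32 site within 100 bp of the start site were bound in 1011 of 3092 cases (32.7%), against 23.9% without one (odds ratio 1.54, Fisher exact p = 5.89e-22). For DREF alone the shares were 38.3% and 24.8%. A TATA box 40 to 20 bp upstream went the other way: 98 of 985 such promoters were bound (9.95%), against 27.1% of the others (odds ratio 0.297, Fisher exact p = 3.45e-38).

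TAATTA was more frequent at summits than in flanks, but the comparisons made here do not separate site recognition from composition. Its ratio of 1.68 ranked 32 of 36 among 6-mers made of A and T alone (percentile 13.9, median ratio 2.09). At random positions of equal A and T content its share was 11.3%, above the 9.72% at summits. Those positions were not matched on location, and 13.5% of them lay at promoters against 43.4% of summits, so composition was not isolated. The share of TAATTA was higher among the 1805 strongest than the 1805 weakest peaks (12.2% against 8.25%, a difference of 3.93 percentage points, interval 1.96 to 5.91), but the strongest summits also held more A and T (69.2% against 63.1%). At equal A and T content the difference was 0.545 points (interval -1.53 to 2.62). Whether TAATTA contributes to strong binding therefore cannot be told apart from composition, and no biological explanation could be set against it with 1 group.

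Summits avoided coding exons. The A and T content of the window alone is not a sufficient explanation. Random positions of equal A and T content fell in coding sequence in 7.42% of cases (6.77% at least), against 0.651% of summits. At promoters they fell in 13.5% of cases, against 43.4% of summits. Other features of sequence composition were not matched. At 85 ribosomal protein and housekeeping genes, 0% of the 102 summits inside them or within 1 kb lay in coding exons (interval up to 3.63%). This does not decide whether reads from highly transcribed genes contribute, since summits in coding exons were rare at all genes and the bound set for this test was met by them already. Open chromatin at promoters and unequal shearing of chromatin stay open, since the control library was not analysed here, and no biological explanation was tested.

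Replicate 2 had fewer relaxed peaks on X than replicate 1, 4924 against 5306 of 30000 (a difference of 1.27 percentage points, interval 0.672 to 1.88). If the replicates differed in their share of males, signal on X could be weaker in replicate 2 at all peak heights; in 3 of 4 equal groups of pooled peaks by signal, the median log2 ratio of replicate 2 to 1 was lower on X than on each of 2L, 2R, 3L and 3R (0.23 against 0.25 to 0.27 for the strongest), though in the next group it was 0.11 on both X and 2R to 2 decimals and in the one after -0.01 against 0.01 on 2R, with 35.6% of peaks lacking a partner. It was not lower in the weakest, where 79.8% of peaks lacked a partner. If the difference lay only near the end of the lists, it would be absent from the 7223 strongest peaks, where X held 16.7% and 16.3% (Fisher exact p = 0.606), but the interval of that difference, -0.878 to 1.54 points, includes the one over all peaks. These explanations cannot be told apart here, since the weakest peaks are too incompletely matched and the sex of the larvae was not collected.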
